A study of Rattus norvegicus with 12 samples.

How the data were processed

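RNA from the renal cortex of Sprague Dawley rats with diabetic nephropathy was sequenced in 12 libraries, 6 from untreated rats and 6 from rats given human placenta-derived mesenchymal stem cells (PMSC). Per the labels' protocols, mRNA was isolated from total RNA with poly-T beads, fragmented and sequenced paired-end on an Illumina instrument. The same protocol also speaks of RNA with or without a poly(A) tail and of an adipose tissue, so the RNA fraction sequenced is uncertain, and with it how much unspliced RNA the libraries held. Groups were taken from the treatment label and replicate numbers from the titles. The labels do not state that the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. They give no batch, sex, age or collection time.

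Per the submitters' processing notes, HISAT2 2.0, StringTie 1.3.0 and Bowtie 0.12.2 were used and the builds rn6 and mm8 were named, with no role or order given. The deposited file holds an estimated count and an FPKM value for each locus in each library. Per the file headers, each locus carries an identifier, gene name, transcript list, coordinates and strand. Coordinates below are those of the file. They are taken as rn6 because the loci carry rat Ensembl identifiers. The deposited estimated counts were already whole numbers, and no rounding was needed. Low estimated counts in the deposited file piled up at 4 and 8 (5140 and 3316 values, against 3434 and 2254 values at 3 and 5), so 1 sequenced fragment is taken as about 4 counts. The deposited FPKM values are normalised by the authors to transcript length and library size. The protocol does not name a strand-marking kit, so reads of a gene and of an antisense partner cannot be told apart.

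The file lists 46452 loci. Of these, 8805 carry no gene name, hold between 3.07% and 4.26% of the counts of a library, and were left out of library sizes and tests. From the 37647 named loci, those with a mean of at least 0.5 FPKM over the 12 libraries were tested, 19811 in all. A locus was called annotated where its transcripts include a rat Ensembl transcript (14313 loci). The remaining 5498 consist of transcripts assembled from the reads alone and are called assembled loci. A further property is that 889 tested loci name several genes, and no list gene was matched to these. Loci of multicopy families, such as the RT1 genes and the ribosomal proteins with their pseudogenes, are uncertain because the file does not say how shared reads were divided.

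The test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The test then written was limma on log2(FPKM + 1), with edgeR to replace it if counts were present. Counts were present, so edgeR 4.0.16 was used (TMM factors, quasi-likelihood fit and test) in R 4.3.3 without covariates. Limma 3.58.1 and DESeq2 1.42.0 served as alternatives. P-values were adjusted by the Benjamini-Hochberg method and called below 0.05. Levels are TMM-scaled counts per 1000000 counts (CPM), as mean ± SD over 6 libraries. Errors of log2 fold changes are standard errors, computed as the fold change over the square root of the F statistic. An adjusted p quoted for a gene without a tool is edgeR's. Total counts ran from 81523653 to 105989618 in a library. The tests were checked on simulated counts for 19811 loci in 6 against 6 libraries, with 50 loci changed at each fold size. At 1.5, 2, 3 and 4-fold, edgeR recovered 8, 52, 86 and 92% of the changed loci, and 3 of its 122 calls were false. DESeq2 recovered 18, 76, 92 and 98%, and 40 of its 182 calls were false (22.0%).

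The fixed gene lists numbered 47. Of their 905 entries, 794 matched a locus, 5 of them through an older symbol in a RefSeq table of assembly GRCr8 that was used for names only. Rorc and Sirt1 had no match and were not analysed here. The matching of older symbols was corrected once after list results had been seen, because some synonyms had led to another gene. The number of lists called was 8 before and after. Lists with at least 5 tested members (40) were tested with camera in limma at a preset correlation of 0.01, then with an estimated correlation and with fry, which asks whether the members move together in 1 direction without comparing them with other genes. A list score is the mean over its members of the standardised log2 CPM. Principal components were computed from centred log2(FPKM + 1) values, and group means of scores and of other single values were compared with two-sided exact permutation tests over all 924 assignments.

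For each direction the 10 largest changes past the threshold with a mean of at least 1 FPKM were to be named, filled by smallest p where fewer passed. Up to 4 members with the smallest p were named for each called list and for the lists of matrix and fibrosis, tubular injury, podocytes, the T helper 17, regulatory T cell and PD-1 axis, and SIRT1, FOXO and autophagy. A set of 14 fixed kidney genes was always given where measured. Because the rule took assembled loci for every lower place, annotated genes with the smallest p in each direction were added after their values had been seen.

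Replicate numbers recur in both groups, and a fit with the number as a block was run as an alternative. Other alternatives were the pseudocount, the filter on low values, the scaling, the test, library weights, a thick ascending limb score as a covariate and each library left out. Libraries were not duplicates, since the nearest pair still differed by 0.80 (root mean square of the log2 difference).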

Results

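Renal cortex transcriptomes were measured by RNA sequencing in 12 libraries from Sprague Dawley rats with diabetic nephropathy. The untreated group and the group treated with human placenta-derived mesenchymal stem cells (PMSC), stromal cells obtained from placenta, held 6 libraries each. Treated rats received 1000000 cells per injection by tail vein weekly for 3 weeks. Healthy rats were not analysed here, so each value is compared with untreated disease only. Total estimated counts in units of 1000000 (M) were 91.1 ± 6.55 M (SD, n = 6) in untreated and 101 ± 3.29 M (SD, n = 6) in PMSC-treated libraries. This difference in total count was larger than the spread (two-sided exact permutation p = 0.00433, adjusted p = 0.0195 over 9 library measures). The totals sum the counts assigned to loci of the file, so they need not equal sequencing depth. At about 4 counts per fragment the libraries held 20.4 to 26.5 M fragments.

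The first comparison asked which transcripts of the diabetic cortex differed after the cell injections. No annotated gene passed edgeR's test, while DESeq2 called 80 annotated loci (48 higher, 32 lower). Among the 10 loci named by the rule on the higher side were Sytl3, a synaptotagmin-like protein that binds Rab GTPases, Rab32, a small GTPase of lysosome-related organelles, and Mrps12, a mitochondrial ribosomal protein. Sytl3 (chromosome 1, 47231093 to 47287371) had 1.98 ± 0.53 CPM in untreated and 3.83 ± 0.57 CPM in PMSC-treated libraries, a log2 fold change of 0.95 ± 0.19 (SE). Rab32 had 25.7 ± 2.74 and 37.0 ± 5.17 CPM, and Mrps12 had 6.16 ± 0.47 and 9.27 ± 1.45 CPM. The other higher-side loci named by the rule were LOC102549061, MGC94199, Dcbld2, Eif1b, Agfg2, LOC691918 and Trmt6, with log2 fold changes between 0.41 and 0.74. In all of these 10 except Dcbld2, every PMSC-treated library lay above every untreated one, and they were chosen for their small p. EdgeR's adjusted p was 0.104 to 0.134. DESeq2 called all 10, with an adjusted p of 0.00044 for Sytl3, 0.00293 for Rab32 and 0.000927 for Mrps12. EdgeR's adjusted p-values here and for the lower-side genes below were computed with the assembled loci included. In edgeR fits chosen after seeing the data, the smallest adjusted p was 0.447 with annotated loci alone and 0.351 with protein-coding loci alone.

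On the lower side the annotated loci with 1 gene symbol and the smallest p, named after their values were seen and leaving out those known only by a clone or locus identifier, were led by Zfp771, a zinc finger protein, at 28.6 ± 3.01 CPM in untreated and 19.5 ± 2.33 CPM in PMSC-treated libraries (adjusted p = 0.104). Ambp, the precursor of alpha-1-microglobulin and bikunin, had 9.33 ± 1.46 and 5.49 ± 1.44 CPM (adjusted p = 0.124). Thrb, the thyroid hormone receptor beta, had 320 ± 36.3 and 222 ± 43.4 CPM (adjusted p = 0.150). Tcf7, a transcription factor of the Wnt pathway, had 15.6 ± 5.20 and 8.66 ± 1.79 CPM (adjusted p = 0.142), and the RNA-binding protein Msi2 had 264 ± 29.0 and 170 ± 48.5 CPM (adjusted p = 0.150). Vwa8, Angptl7, Tmem253, Mbtd1 and Camta1 had log2 fold changes between -0.94 and -0.39. On the higher side the same choice added Tgm3, Prpf18 and Nuak2, an AMPK-related kinase, which had 139 ± 36.4 and 234 ± 52.9 CPM (adjusted p = 0.142). DESeq2 called Zfp771 (adjusted p = 0.000741), Ambp (0.00748), Tcf7 (0.0173), Thrb (0.0271) and Msi2 (0.0373), but not Mbtd1 (0.0512) or Camta1 (0.0523).

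In total, edgeR's quasi-likelihood test called 0 of 19811 loci, with a smallest adjusted p of 0.0781. At an unadjusted p under 0.05 there were 2313 loci, 551 higher and 1762 lower in PMSC-treated libraries, where 991 would arise by chance alone. This split was 660 higher and 1083 lower with limma after quantile normalisation, which also called 0 loci. Of the 2313 loci, 1447 were assembled (26.3% of 5498) and 866 were annotated (6.05% of 14313). The annotated ones were 508 higher and 358 lower in this fit. With annotated loci fitted alone, a choice made after seeing the data, 236 were higher and 555 lower. DESeq2 called 445 loci, 53 higher and 392 lower, and 365 of the 445 were assembled loci without an annotated transcript. In simulated data of this size 22.0% of DESeq2's calls were false, against 2.46% of edgeR's. The simulated loci varied independently, with the spread estimated by edgeR and no library or class of loci set apart. These percentages therefore do not give the false share of the 445 calls.

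The lower side was made up mainly of assembled loci lying inside known genes. The 10 named by the rule carry the names Klf13, Mllt10, Atf7, Fam107b, Map7, Clint1, Ak4, H2afy, Vwa8 and Igf1r, and none holds an annotated transcript. The locus inside Klf13 (chromosome 1, 124781640 to 124788543) had 14.8 ± 3.44 CPM in untreated and 7.02 ± 0.57 CPM in PMSC-treated libraries, a log2 fold change of -1.08 ± 0.15 (SE, adjusted p = 0.0781). The locus named Ak4 (chromosome 5, 120282283 to 120301632) had 118 ± 39.6 and 46.5 ± 8.90 CPM, and the one named Vwa8 (chromosome 15, 61101025 to 61106029) had 23.0 ± 3.63 and 8.90 ± 3.75 CPM, both with an adjusted p of 0.0998. In each of these 10 loci, chosen for their small p, every PMSC-treated library lay below every untreated one. Without PMSC replicate 6, edgeR called 5 loci, all lower and all assembled, with the names Vwa8, Fam107b, Msi2, Fras1 and Add1, listed here after their values were seen.

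Taken as a class, 78.6% of the 5498 assembled loci were lower in PMSC-treated libraries, with a median log2 fold change of -0.33, against a median of 0.07 for the 14313 annotated loci. This class fell relative to the annotated loci (camera p = 2.95e-33 with the preset correlation, p = 0.00175 with an estimated correlation). With limma the class median was -0.18 on log2(FPKM + 1), -0.30 and -0.33 with pseudocounts of 0.1 and 0.01, -0.26 on TPM and -0.10 after quantile normalisation, and in edgeR with a filter of 5 FPKM it was -0.085, against 0.018 for annotated loci. Assembled loci located within an annotated locus of the same name (3547) were lower in 86.0%, with a median of -0.40. Summed over these, their counts came to 14.5 ± 1.77% of the counts of the host genes in untreated and 10.99 ± 1.48% in PMSC-treated libraries (SD, n = 6 each, two-sided exact permutation p = 0.00866). In 1552 of 1763 host genes (88.0%) the assembled loci had a lower fold change than the host, whose median was 0.04. The share of counts at unnamed loci was 3.89 ± 0.30% and 3.23 ± 0.17% (exact permutation p = 0.00433, adjusted p = 0.0195). The group with fewer assembled-locus counts also had higher total counts, as given above.

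**Figure D1:**
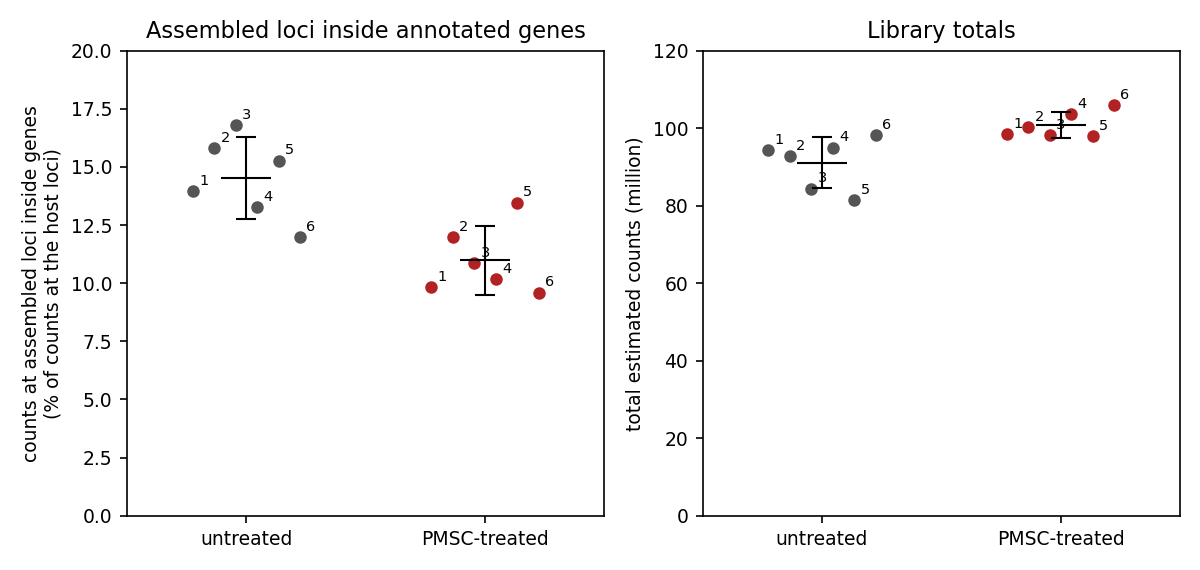
The left panel shows counts at assembled loci inside annotated genes as a percentage of the counts at the host genes, and the right panel the total estimated count in M, with 1 numbered point per library and bars for mean ± SD. Untreated libraries reached up to 16.8% and PMSC-treated libraries lay between 9.59 and 13.5%.

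The second comparison asked which pathways and cell types differed. Of 40 lists, camera with a preset correlation called 8. In 7 of them the members were higher in PMSC-treated libraries, namely nuclear-encoded oxidative phosphorylation, MHC class II and antigen presentation, tubular injury markers, extracellular matrix and fibrosis, complement and coagulation, cytosolic ribosomal proteins, and glycolysis. In 1 list, the immediate early genes, they were lower. In this fit only 34.6% of all annotated loci were lower, so the counts of higher members below are to be read against that share. None of the 8 held with an estimated correlation, with fry, or with a permutation of the list scores. In edgeR none of their members passed over all loci tested, and 0 passed when adjusted over the list alone. DESeq2 called 3 members over all loci, namely Egr1 (adjusted p = 0.0124), Nr4a2 (0.0317) and Col4a2 (0.0441). With annotated loci alone as the background, a choice made after seeing the data, 7 lists were called, 6 of the 8 and the circadian clock genes. With the share of assembled-locus counts as a covariate, also chosen after seeing the data, 2 lists were called, and 1 of the 8 was among them, the ribosomal proteins, in the opposite direction. That share was itself 5.69 ± 0.64% in untreated and 4.55 ± 0.48% in PMSC-treated libraries (SD, two-sided exact permutation p = 0.0108). The covariate is thus tied to the groups, and this fit cannot cleanly tell it from the treatment.

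Tubular injury markers were higher, 19 of 20 measured members having a positive log2 fold change (median 0.39, adjusted p = 0.00179, but adjusted p = 0.563 with an estimated correlation). Havcr1, which encodes kidney injury molecule KIM-1, had 4.78 ± 1.79 CPM in untreated and 115 ± 270 CPM in PMSC-treated libraries (adjusted p = 0.241). Lcn2, encoding the injury marker NGAL, had 3.49 ± 1.03 and 12.6 ± 19.0 CPM, Spp1 (osteopontin) had 207 ± 90.1 and 527 ± 642 CPM, and Cd24 had 128 ± 23.6 and 213 ± 134 CPM. These means were set by PMSC replicate 3, which held 65228 counts of Havcr1 where the other libraries held 178 to 780, and 5019 counts of Lcn2 against 129 to 599. The same library was lowest for Umod (uromodulin, made in the thick ascending limb), at 20743 counts. Without PMSC replicate 3, Havcr1 had a log2 fold change of -0.07 ± 0.40 (SE), Lcn2 of 0.49 ± 0.25, Spp1 of 0.37 ± 0.33 and Cd24 of 0.31 ± 0.16, and the list was not called (median 0.12, adjusted p = 0.196).

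Complement and coagulation genes showed the same dependence. Of 20 measured members 19 were higher in PMSC-treated libraries (median 0.38, adjusted p = 0.0056, but adjusted p = 0.563 with an estimated correlation). Among them were the fibrinogen chains. Fgb had 3.08 ± 0.99 and 45.1 ± 102 CPM, Fga had 25.2 ± 7.60 and 125 ± 222 CPM, and Fgg had 0.15 ± 0.13 and 2.61 ± 5.96 CPM. C1r, a protease of the classical complement pathway, had 31.6 ± 3.47 and 42.4 ± 12.3 CPM. PMSC replicate 3 held the highest fibrinogen counts (56624 for Fga). Without it the log2 fold changes went from 3.87 to 0.25 ± 0.29 (SE) for Fgb, from 2.31 to 0.43 ± 0.22 for Fga and from 4.10 to 0.24 ± 0.72 for Fgg, and the list was not called (median 0.14, adjusted p = 0.226).

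**Figure D2:**
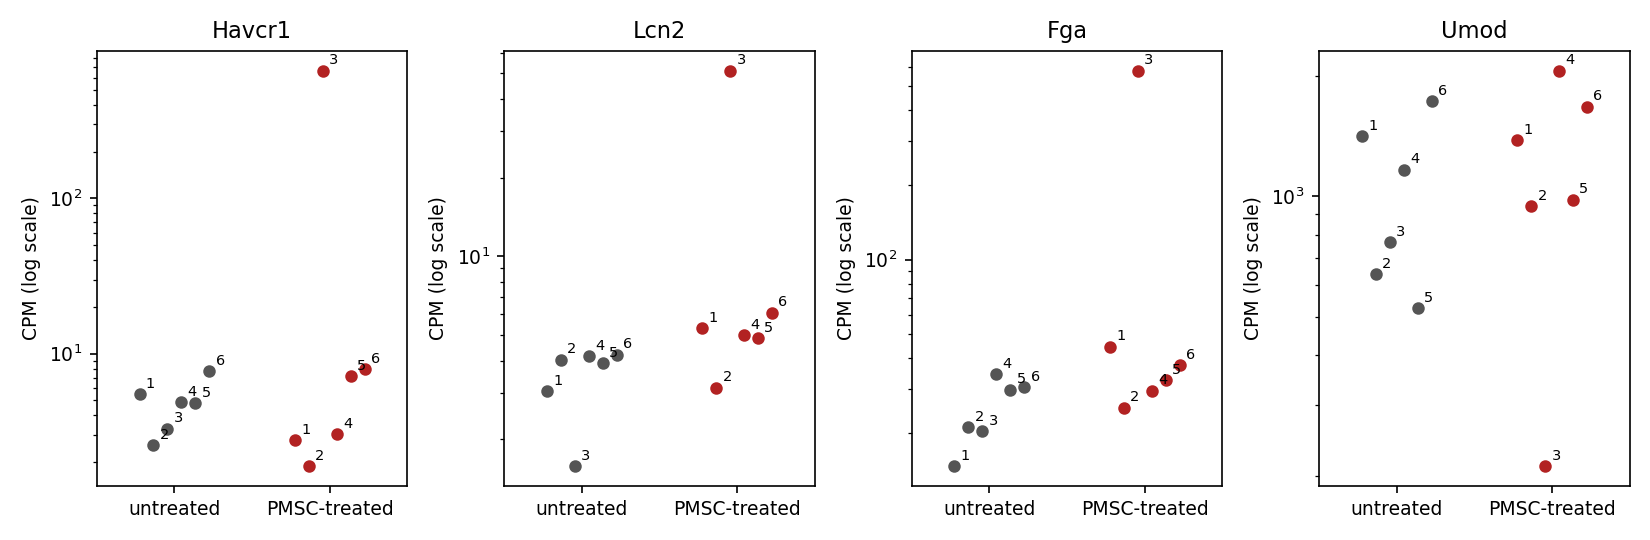
Levels of Havcr1, Lcn2, Fga and Umod in CPM on a logarithmic axis, with 1 numbered point per library and no error bars. PMSC replicate 3 reached 666 CPM for Havcr1 and 578 CPM for Fga and lay lowest for Umod at 212 CPM.

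MHC class II and antigen presentation genes, which load and display peptides to T cells, were higher in 12 of 13 measured members (median 0.38, adjusted p = 0.00169, but adjusted p = 0.563 with an estimated correlation). Their master regulator Ciita had 4.18 ± 0.91 CPM in untreated and 6.56 ± 1.72 CPM in PMSC-treated libraries (adjusted p = 0.228). The class II genes RT1-Db1, RT1-Ba and RT1-Bb had 20.8 ± 7.05 and 39.3 ± 21.7 CPM, 14.3 ± 7.90 and 32.5 ± 17.5 CPM, and 11.7 ± 6.79 and 19.7 ± 7.26 CPM. Without PMSC replicate 3 the list's median was 0.20 (adjusted p = 0.0464) and RT1-Db1 had a log2 fold change of 0.61 ± 0.34 (SE) in place of 0.92 ± 0.37. With annotated loci alone and that library left out the adjusted p was 0.121. Macrophage and dendritic cell markers, 17 of 18 higher in sign, were not called (adjusted p = 0.150). They were called without PMSC replicate 6 and with the thick ascending limb score as a covariate. Both of these fits kept PMSC replicate 3, whose score for this list was 1.84, where the other libraries lay between -0.77 and 0.54.

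Extracellular matrix and fibrosis genes were higher in 21 of 25 measured members (median 0.22, adjusted p = 0.00179, but adjusted p = 0.563 with an estimated correlation). Basement membrane collagen genes Col4a2 and Col4a1 had 107 ± 12.1 and 156 ± 37.8 CPM, and 157 ± 33.1 and 233 ± 86.7 CPM. Lox, which cross-links collagen, had 6.09 ± 2.78 and 12.04 ± 4.68 CPM, and Col5a1 had 10.7 ± 2.41 and 14.2 ± 3.48 CPM. Col1a1 had 17.1 ± 11.5 and 18.0 ± 1.59 CPM and Fn1 had 78.2 ± 30.7 and 83.7 ± 23.4 CPM. Untreated replicate 4 was highest for Col1a1 at 40.3 CPM, and without it the log2 fold change of Col1a1 was 0.53 ± 0.13 (SE, adjusted p = 0.165) in place of 0.07 ± 0.30. The list's median was 0.36 without that library (adjusted p = 1.47e-05) and 0.13 without PMSC replicate 3 (adjusted p = 0.0464). With annotated loci alone and PMSC replicate 3 left out the list was not called (median 0.07, adjusted p = 0.203), nor with a filter of 5 FPKM (adjusted p = 0.386).

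Energy metabolism and translation lists shifted by small amounts. Nuclear-encoded oxidative phosphorylation genes were higher in 39 of 42 members (median 0.13, adjusted p = 0.00169, but adjusted p = 0.585 with an estimated correlation), with Uqcrc1 at 222 ± 29.0 and 264 ± 26.4 CPM, Uqcrc2 at 349 ± 26.3 and 398 ± 23.3 CPM, Ndufa7 at 34.5 ± 4.49 and 40.01 ± 5.26 CPM and Cyc1 at 92.4 ± 18.8 and 109 ± 14.7 CPM. Cytosolic ribosomal protein genes were higher in 35 of 39 (median 0.12, adjusted p = 0.0131, but adjusted p = 0.637 with an estimated correlation), among them Rps14 at 74.5 ± 8.24 and 85.8 ± 8.07 CPM, Rpl24, Rps20 and Rps3. Glycolysis genes were higher in 15 of 16 (median 0.17, adjusted p = 0.0131, but adjusted p = 0.563 with an estimated correlation), with Pgam1 at 257 ± 19.0 and 292 ± 25.8 CPM, Pfkp at 27.1 ± 8.18 and 32.9 ± 4.75 CPM, Hk1 at 89.4 ± 20.4 and 106 ± 18.0 CPM and Slc2a1, the glucose transporter GLUT1, at 37.3 ± 6.69 and 43.6 ± 8.73 CPM. With annotated loci alone as the background the medians were 0.077 for oxidative phosphorylation, 0.059 for ribosomal protein and 0.12 for glycolysis genes. The ribosomal (adjusted p = 0.277) and glycolysis (adjusted p = 0.109) lists were not called there. All 3 lists lost their call with quantile normalisation and a filter of 5 FPKM. With the share of assembled-locus counts as a covariate, added after seeing the data, their medians turned to -0.14, -0.21 and -0.081, but that share itself differed between the groups. Without untreated replicate 6 the ribosomal median was 0.22 (adjusted p = 0.000226). The call of the ribosomal list ended without untreated replicate 2 (adjusted p = 0.132), untreated replicate 3 (0.0625) or PMSC replicate 1 (0.0819), and that of glycolysis without untreated replicate 5 (0.0953) or PMSC replicate 3 (0.0678).

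Immediate early genes, transcription factors and signalling feedback genes that respond within minutes to stimuli, were lower in PMSC-treated libraries in 15 of 20 members (median -0.62, adjusted p = 0.00373, but adjusted p = 0.585 with an estimated correlation), and 8 members had an unadjusted p under 0.05. Egr1 had 114 ± 93.8 CPM in untreated and 36.8 ± 11.7 CPM in PMSC-treated libraries (adjusted p = 0.180). Nr4a2 had 17.2 ± 14.8 and 5.30 ± 1.91 CPM, Fos had 23.3 ± 14.5 and 10.6 ± 4.68 CPM, and the phosphatase gene Dusp1 had 75.1 ± 55.0 and 38.3 ± 9.31 CPM. Untreated replicate 1 carried the highest list score (1.72), and without it the log2 fold change of Dusp1 went from -0.97 to -0.51 ± 0.29 (SE) and that of Egr1 from -1.64 to -1.11 ± 0.35, the median was -0.27 and the list was not called (adjusted p = 0.154), although it was with annotated loci alone as the background and that library left out (adjusted p = 0.0101).

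**Figure D3:**
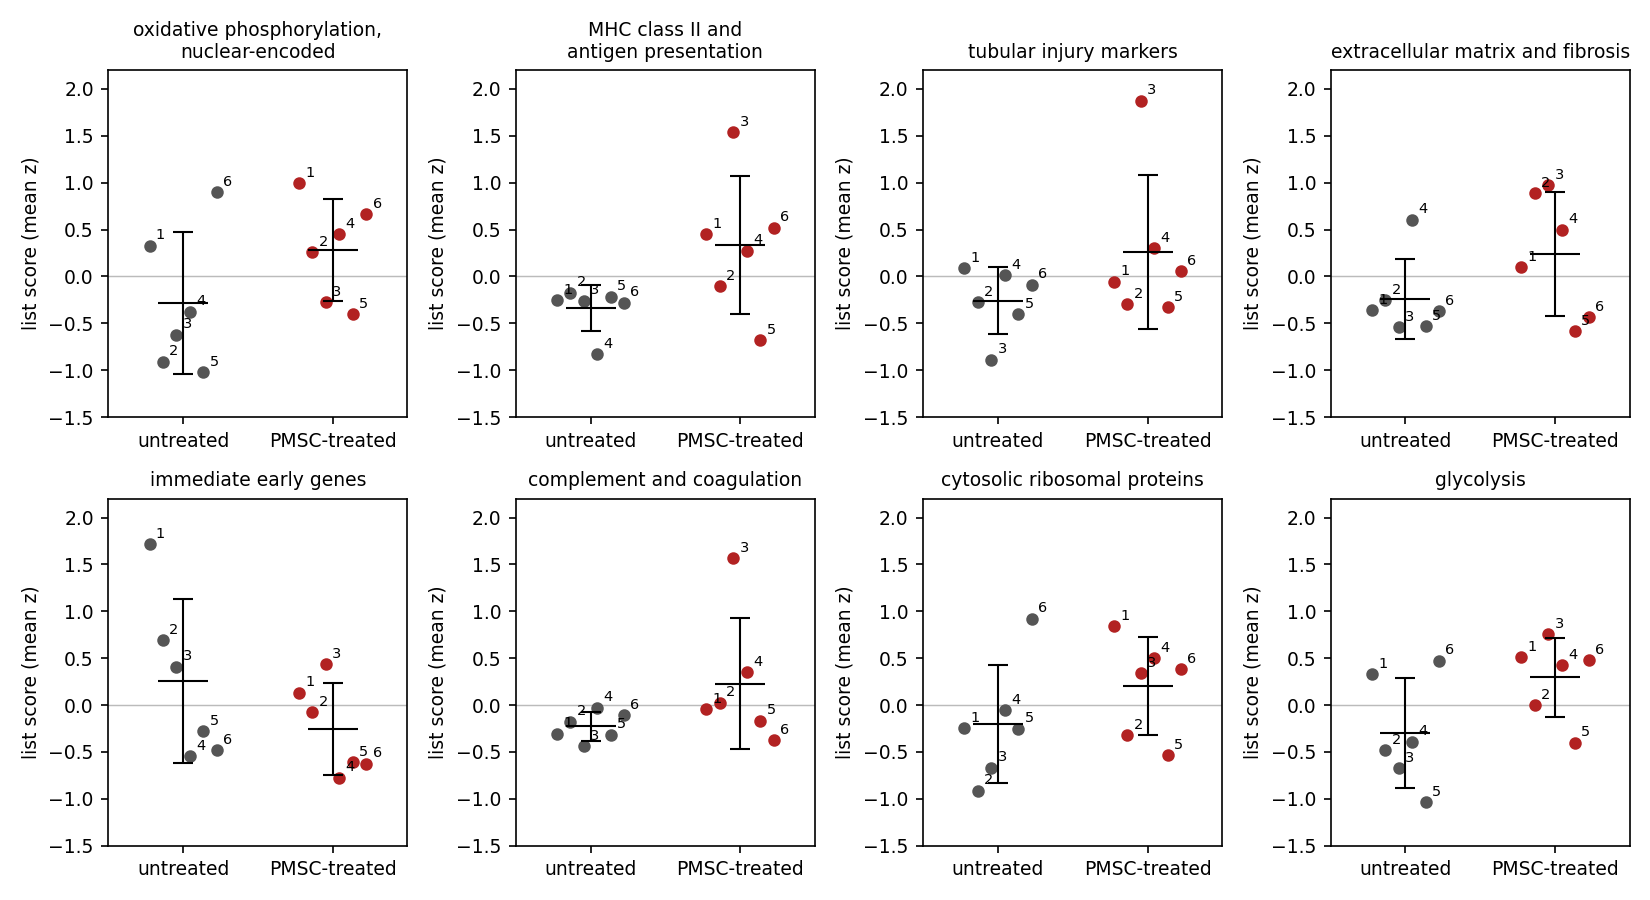
Scores of the 8 called lists, each the mean standardised log2 CPM over its members, with 1 numbered point per library and bars for mean ± SD. PMSC replicate 3 scored 1.87 for tubular injury and 1.57 for complement and coagulation, and untreated replicate 1 scored 1.72 for immediate early genes.

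Lists tied to the disease or the treatment that were not called are given for their levels. Podocyte markers, from the filtering cells of the glomerulus, were higher in sign in 16 of 18 (adjusted p = 0.129). They were called without untreated replicate 2, without PMSC replicate 1 and with the thick ascending limb score as a covariate. Nphs1 (nephrin) had 92.9 ± 27.3 and 98.99 ± 28.2 CPM, Nphs2 (podocin) 95.9 ± 29.5 and 115 ± 27.7 CPM, and Podxl 557 ± 164 and 676 ± 138 CPM. Npnt and Thsd7a had log2 fold changes of -0.15 and 0.17. For the T helper 17, regulatory T cell and PD-1 axis 6 members were measurable (adjusted p = 0.301), with Foxp3 at 2.95 ± 0.38 and 2.94 ± 0.53 CPM, Cd274 (PD-L1) at 1.70 ± 0.29 and 1.95 ± 0.48 CPM, Tgfb1 at 9.85 ± 0.56 and 11.4 ± 3.58 CPM, Stat3 at 159 ± 24.8 and 219 ± 72.4 CPM, and Ikzf2 at 9.79 ± 1.70 and 9.06 ± 1.15 CPM. The SIRT1, FOXO and autophagy list had an adjusted p of 0.150, with Atg5 at 24.6 ± 2.89 and 29.0 ± 3.83 CPM, Sqstm1 at 411 ± 39.2 and 479 ± 65.8 CPM, Map1lc3a at 19.9 ± 3.88 and 23.5 ± 3.01 CPM, and Foxo1 at 137 ± 15.7 and 121 ± 19.6 CPM. Slc5a2, the glucose transporter SGLT2, had 74.4 ± 38.1 and 73.6 ± 40.4 CPM, Umod had 1039 ± 474 and 1208 ± 645 CPM, and Ccl2 had 0.51 ± 0.31 and 0.99 ± 1.38 CPM. Without PMSC replicate 3, which held 370 counts of Ccl2 where the other libraries held 19 to 98, the log2 fold change of Ccl2 went from 0.97 to -0.23, that of Umod from 0.22 to 0.44, Stat3 from 0.47 to 0.27, Tgfb1 from 0.22 to 0.045, Cd274 from 0.20 to 0.069 and Foxo1 from -0.18 to -0.10. That of Slc5a2 went from -0.016 to -0.30 and that of Ikzf2 from -0.11 to -0.060. Without PMSC replicate 4 that of Umod (MSTRG.2330) was -0.00185. None of these genes passed, and the smallest adjusted p among them was 0.353, for Stat3.

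The third comparison asked whether the leading differences among libraries followed treatment. Component 3, with 10.7% of the variance, separated the groups. Scores were 13.8 ± 10.3 in untreated and -13.8 ± 8.33 in PMSC-treated libraries (SD, n = 6 each), and the two-sided exact permutation p of 0.00216 is the smallest that the design allows (adjusted p = 0.00649 over 3 components). Of the 200 loci with the largest loadings on it, 101 were assembled loci, which make up 27.8% of the tested loci. Component 1 (24.1%) and component 2 (16.5%) did not separate the groups (exact permutation adjusted p = 0.351 and 0.968). Havcr1, Fgb and the chemokine gene Ccl20 were among the 10 largest loadings of component 2, on which PMSC replicate 3 lay lowest at -51.0. The separation was no longer called without PMSC replicate 3 (smallest adjusted p = 0.0747), without PMSC replicate 5 (0.0909) or with a filter of 5 FPKM (0.597).

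**Figure D4:**
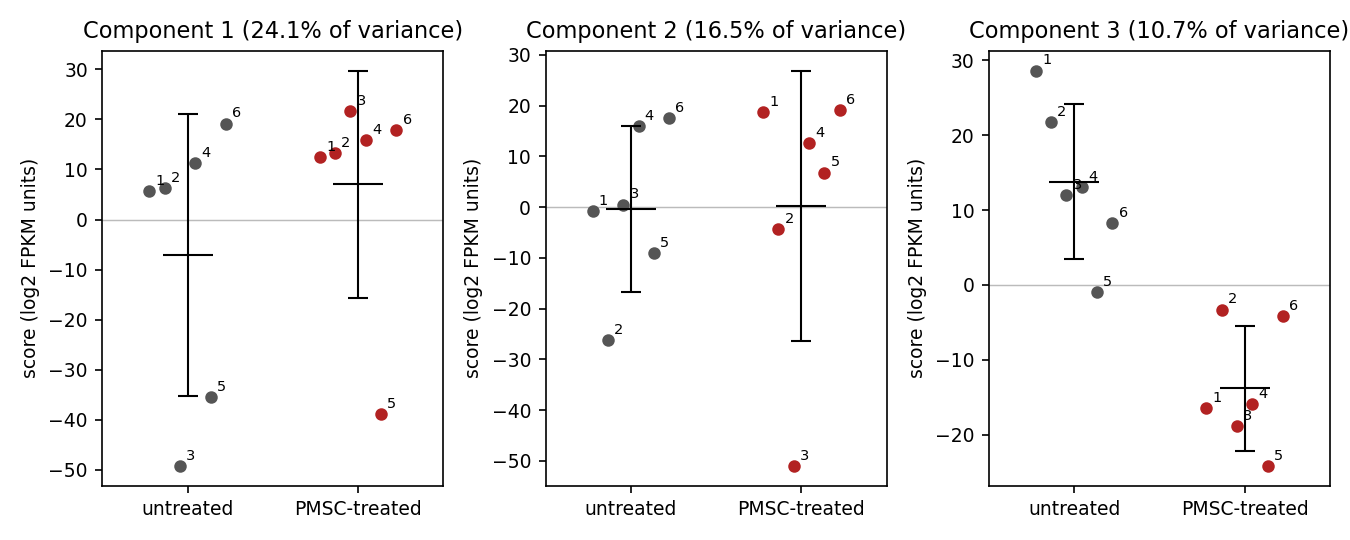
Scores of the 12 libraries on principal components 1 to 3 of centred log2(FPKM + 1) values, with 1 numbered point per library and bars for mean ± SD. On component 3 the untreated libraries lay between -0.92 and 28.6 and the PMSC-treated libraries between -24.2 and -3.30.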

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

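The tests of unspliced RNA, of its strand, of classes of 1, 2 and 5 FPKM and of the share of thick ascending limb were chosen only after the results they measure had been seen. In 20 of 204 groups of 6 values, 1 library lay far from the other 5 relative to the group's range. Chance would give 10.2 in groups picked without regard to their values. Many were genes named for a small p or scores of called lists, so this number is only a guide. PMSC replicate 3 gave 10 of the 20, among them genes and scores of lists whose call rested on it. Gene levels in this part are log2 CPM.

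Assembled loci without an annotated transcript were lower in PMSC-treated libraries. Genomic DNA carried over would add a constant signal and so weigh less at higher FPKM. The group difference was -0.30 ± 0.10 (SE, log2) in the 1833 assembled loci of lowest FPKM. In the 1833 of highest FPKM (median 2.59) it was -0.25 ± 0.06, a ratio of 0.832. Over 5 FPKM the difference was -0.037 ± 0.035 (309 loci), as carried-over DNA would give. At 2 to 5 FPKM it was -0.29 ± 0.07 and under 1 FPKM -0.30 ± 0.11, so that the difference did not weaken up to 5 FPKM. Such DNA would also add alike inside and outside annotated genes, but loci inside differed by -0.21 ± 0.04 more than the others at 1 to 2 FPKM and by -0.23 ± 0.08 more over 5 FPKM (SE), which argues against it as the whole cause. More unspliced RNA in the untreated libraries stays open: loci inside an annotated gene differed by -0.22 ± 0.04 more than the other assembled loci (two-sided exact permutation p = 0.00216, the smallest possible), as it would give, but inside loci recorded on the opposite strand of the host differed by -0.39 ± 0.08 (1926 loci) and those on its strand by -0.41 ± 0.09 (509 loci), which it would not give if the recorded strands hold, and the kit is not said to mark strands. A difference in total count stays open, since with total count as a covariate the log2 ratio of these counts to those of the host genes went from -0.40 ± 0.11 to -0.19 ± 0.12 (SE), and the groups differ in total count. An effect of the treatment on splicing or nuclear RNA was not tested and stays open, as does a library batch, for which there is no label.

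PMSC replicate 3 was the highest of its group for Havcr1 (9.38, others 0.94 to 2.99), Lcn2 (5.68, others 1.67 to 2.61), Cd24 (8.91, others 6.88 to 7.55), Fgb (7.98, others 0.89 to 2.46), Fga (9.18, others 4.66 to 5.48) and Fgg (3.89, others -3.55 to -1.66), and the lowest for Umod (7.73, others 9.88 to 11.01). Its scores were 1.87 for tubular injury and 1.57 for complement and coagulation, and it lay at -51.0 on component 2. Liver tissue in the sample would bring albumin and apolipoprotein transcripts, but their median rise was 0 times the rise of Fgb and Alb had 0 counts, which argues against it. A smaller share of thick ascending limb alone in the piece, whose marker score was -1.10, would raise the other cell types alike. The proximal tubule S3 score was also the lowest of all libraries (-1.39), while the macrophage and dendritic cell score was the highest (1.84). These values argue against a loss of thick ascending limb alone as the whole cause. A piece poorer in both segments was not tested and stays open. No biological explanation was tested, and injury of this kidney, whether or not related to the treatment, and a sample from outside the 2 groups stay open. A swapped group label would not set it apart from both groups, whose other libraries held at most 780 counts of Havcr1.

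Other values far from their group were as follows. The assembled locus inside Atf7 was at 1.28 in untreated replicate 6, where the others lay between 1.64 and 1.66. Spp1 was at 8.61 and Stat3 at 6.80 in the same library, against 7.30 to 7.50 and 7.25 to 7.49. Lcn2 was at 0.68 in untreated replicate 3, against 1.62 to 2.08. Col1a1 was at 5.33 in untreated replicate 4, against 3.21 to 3.91, and that library scored 0.61 for extracellular matrix and fibrosis and -0.83 for MHC class II and antigen presentation. PMSC replicate 5 had Map1lc3a at 4.16, against 4.52 to 4.73, RT1-Ba at 2.32, against 4.63 to 5.81, and -38.8 on component 1, against 12.5 to 21.6. This place on component 1 was not particular to it, since untreated replicates 3 (-49.2) and 5 (-35.5) lay on the same side. The share of counts at small nuclear RNA loci was highest in untreated replicates 3 (3.74%) and 5 (3.14%) and PMSC replicate 5 (2.67%).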

How the results depend on the processing

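Alternatives chosen after seeing the data were annotated, protein-coding or unnamed loci, the covariate of assembled-locus share, annotated loci with a library left out, counts divided by 4 and robust edgeR. Limma, the test first written, was kept beside edgeR once counts were seen, and carries the planned pseudocount, quantile, TPM and weight settings. The count of loci called, 0 with edgeR, became 445 with DESeq2 (53 higher, 392 lower), 379 with DESeq2 on counts divided by 4, and 45 with limma and library weights, of which 42 were assembled loci. Unadjusted p under 0.05 with at least 2-fold change gave 299 loci. Leaving out 1 library gave 0 to 5. In the other alternatives of this count edgeR and limma called 0, as did the exact rank-sum test. That test recovered 0% of simulated 4-fold changes and so decides nothing. Loci at an unadjusted p under 0.05 numbered 292 of 6960 with a filter of 5 FPKM and 791 of 14313 with annotated loci alone. The number of lists called, 8, became 0 with an estimated correlation, 0 with fry, 4 with a filter of 5 FPKM (3 of the 8 among them), 2 with the covariate of assembled-locus share (1 of the 8), and 5 with annotated loci alone and PMSC replicate 3 left out (2 of the 8). Leaving out 1 library gave 7 to 12 lists. With that covariate, which itself differed between the groups, the medians of oxidative phosphorylation (-0.14), ribosomal protein (-0.21) and glycolysis genes (-0.081) had the opposite sign. Components that separate the groups numbered 0 with a filter of 5 FPKM, and 0 to 1 with 1 library left out. The cause was not tested. Whether replicate numbers pair the groups is not settled. With group means removed, 2 of 6 untreated libraries correlated best with the PMSC-treated library of their own number. Correlations between libraries of the same number ran from -0.11 to 0.22. The replicate block gave 0 loci (2617 at unadjusted p under 0.05) and 8 lists. Of the 84 named entries none was called in the main fit, so none could lose a call. Over 33 alternatives 2619 results stayed uncalled, which does not measure how stable their values are. The threshold was passed by 84 results, under DESeq2, library weights or without PMSC replicate 6. In 19 entries the sign changed in some alternative without a call. At the depth, spread and number of these libraries edgeR recovered 8% of 1.5-fold changes in simulated data, and which of them limits it was not tested.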

Other observations

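The settings with annotated loci alone and with the share of assembled-locus counts as a covariate were chosen only after the data had been seen. That share itself differed between the groups. Of 17 measured circadian clock genes, 8 had a positive and 9 a negative log2 fold change. The activators Arntl (BMAL1) and Npas2 had 14.0 ± 6.81 and 30.5 ± 13.1 CPM, and 3.69 ± 1.57 and 9.06 ± 5.42 CPM, in untreated and PMSC-treated libraries (SD, n = 6 each). The repressors Per1, Per2 and Per3 had log2 fold changes of -0.55, -0.68 and -0.80, and Nr1d2 (REV-ERB beta) of -0.54. Clock, Cry1, Nr1d1, Bhlhe40 and Bhlhe41 had values between 0.02 and 0.10. In edgeR none passed over all loci, and 2 did when adjusted over the list alone. The list was not called (median -0.21, adjusted p = 0.129, and adjusted p = 0.563 with an estimated correlation), but was called with the planned filter of 5 FPKM (8 members, median -0.31, adjusted p = 0.000127), with that covariate (median -0.53, adjusted p = 0.0412) and against annotated loci alone (adjusted p = 0.00182), a background without the assembled loci that were lower. PMSC replicate 6 had 8.03 CPM of Arntl, where the other PMSC-treated libraries had 27.7 to 45.6 CPM, and without it the log2 fold change of Per3 was -1.26, those of Nr1d1 and Bhlhe41 were -0.25 and -0.10, and the list was called (adjusted p = 0.0142). Kidneys collected at another time of day may be a source of these values. Output genes (Usp2, Wee1, Tspan4 and Por) differed by -0.671 in mean score (exact permutation p = 0.115), which leaves that open, and no collection time is given.

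Glucocorticoid-responsive genes, which overlap the clock and injury lists, were not called (adjusted p = 0.857), though 4 members passed when adjusted over the list alone. Errfi1, a feedback inhibitor of EGF receptor signalling, had 1203 ± 415 and 773 ± 76.2 CPM. Among cell types, the adjusted p was 0.129 for endothelial, 0.201 for thick ascending limb, 0.284 for T and NK cell, 0.301 for principal cell, 0.451 for intercalated cell, 0.516 for smooth muscle and mesangial, 0.793 for proximal tubule and 0.984 for red blood cell lists. Cholesterol synthesis (0.0608), heat shock (0.0749) and interferon-stimulated genes (0.0839) came nearest to a call, and the other tested lists reached up to 0.987. The test pointed up while the median was negative for proximal tubule, red blood cell and gluconeogenesis lists. The S3 segment list pointed up with a negative mean, the distal convoluted tubule list down with a positive mean, and the glucocorticoid list down with a median of 0.0020.

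Lists with fewer than 5 members past the filter were not tested. Adipocyte markers (Adipoq, Cfd, Cidec and Fabp4 passed) summed to between 2666 and 16021 counts in a library. B and plasma cell markers summed to 1367 to 4322, neutrophil markers to 49 to 300, adrenal cortex markers to 109 to 205, skeletal muscle markers to 150 to 373 and sex-linked genes to 7285 to 10043. Mitochondrially encoded transcripts summed to 0 to 2 counts, and 1 of 37 mitochondrial loci in the file was above 0, so these transcripts are in effect absent from the file.

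The real grouping was set against other splits of the 12 libraries into 6 and 6, for 100 splits with the real one included. Of 462 possible splits, only these 100 were drawn. DESeq2's 445 loci were the most (highest other 190, median of the others 8), reached in 1 of 100, so chance is unlikely for that count but not excluded. The 2313 loci of edgeR at unadjusted p under 0.05 (highest other 2389) and the gap of 0.3996 between the medians of annotated and assembled loci (highest other 0.4003) were each reached in 2 of 100. This is under the 5 of 100 set beforehand, so chance is unlikely there at that threshold only. The split that went higher on both exchanged untreated replicate 1 with PMSC replicate 5. For edgeR's 0 adjusted calls (highest other 10) the comparison decides nothing, because any split gives at least 0. At least 8 lists were called in 70 of 100 (highest other 21), so chance cannot be excluded for the lists.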
